A study of Mus musculus with 52 samples.

How the data were processed

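The organoids are described in the labels as intestinal, from wild type C57BL/6 mice of 8 weeks. Per the labels' protocols, 50000 single cells were seeded per well, RNA of 3 wells was pooled and DNase-treated, and libraries were made with a TruSeq mRNA kit. Until day 3 the medium held EGF, Noggin and R-spondin with 20% Wnt3a-conditioned medium, 10 µM Y-27632 and 3 µM CHIR99021, and from then on the growth factors without these additions. The design text counts 4 treatment conditions and the labels name 3 (DMSO, atRA and RXRi), which are the ones analysed here. bcl2fastq 2.17, STAR 2.5.2b and the genome build mm10 are named in the submitters' processing notes, without their settings. The counting tool, its annotation and its use of strand are not given in the sources used here, so reads of overlapping, antisense or near-identical genes cannot be told apart.

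The authors deposited 1 table of RPKM, reads scaled to gene length and library total, per the file headers, with a column for each of the 52 libraries, which were matched to the labels by title. All columns were used. RPKM divides by the total of each library, so a large rise of some genes lowers the values of others. The values of all 19708 genes above 0 came out as whole multiples of a read within a tolerance of 0.001 of a read, and these reads were used for depth, for thinning and for 1 alternative, not for the main test. Depths and genes above 0 per library are given with the results, with 3 reads as the floor for a single gene, which covers counting error only.

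Values were taken as log2(RPKM + 1), a scale that understates changes of low genes. The duplicates of a culture were averaged on that scale, which gave 26 culture means, so n = 2 cultures per group throughout. Genes with at least 1 RPKM in at least 4 libraries were tested, 12445 of them, and 11671 were left out. limma 3.58.1 in R 4.3.3 was fitted over all 13 groups at once (trend and robust options, 13 residual degrees of freedom), so that they share an estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment within each comparison and a threshold of 0.05, and ± after a log2 fold change is the standard error of that fit. The comparisons were the DMSO steps from day to day, each drug against DMSO on each of 4 days and over their mean, atRA against RXRi over the mean, and the day 5 effect minus the day 1 effect of each drug.

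Before the data were examined, 40 gene lists were written from general knowledge of the tissue and of retinoid signalling, and 35 with at least 5 measured members were tested with camera (limma), which asks whether a list moved more than the other genes. Its preset correlation was 0.01, and results are given also with a correlation estimated from the data, except some with a library left out. Adjustment was over the 35 lists of a comparison. Several lists share genes and cell types, so their results are not independent. The named genes follow rules written at the same time. They are the 10 largest changes each way of each mean over days with 1 sign on all 4 days, the 3 largest each way of each drug and day and the 5 largest each way of each DMSO step with 1 sign in both cultures. To these come up to 4 members with the smallest p of each list described, the retinoic acid and retinoid X receptor genes with the retinoic acid-induced list, and the 5 largest each way of each change with time. Predicted gene models were counted and not named, and the text gives a part of the genes that the rules allow. Some genes that the rules name are not reported here.

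Gene coordinates are those of GRCm38.p6, the patch series of mm10, from a RefSeq gene table matched by Entrez identifier, 1-based, and 12430 of the tested genes (99.9%) had a match. The pairing of cultures comes from the animals, per the labels: deviations of the same culture from the group means correlated with a median r of 0.142 over 78 pairs of groups (-0.317 to 0.759), with 47 pairs above 0.1. The culture was left out of the main fit and kept as a block in an alternative. Duplicates differed by more than counting error, with chi-square per degree of freedom of 1.94 to 14.4 over 25 pairs, against 5.01 to 102 between cultures. Of all 1326 pairs of libraries, 0 held identical values.

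The fit was tested on simulated data with known changes, drawn for the real groups. For atRA against DMSO on day 3, 53 of 65 genes changed 4-fold were recovered (81.5%) and 28 of 67 changed 2-fold (41.8%), with 1 of 11099 unchanged genes called, over 11319 genes. These were 65, 62 and 8 without the shallow library. For atRA on day 1, 27 of 11119 unchanged genes were called, and 14 without that library. The simulated shallow library held few reads, all drawn from its own group. These counts therefore do not cover the reads in the real library that resemble other groups. A list raised by 1.5-fold was called for atRA on day 3, and 0 of 31 other lists were. The simulated genes varied independently of each other. This result therefore does not cover false list calls from genes that vary together, as those of a list may in the real data. Alternatives fixed before the data were examined were a pseudocount of 0.1, no filter, median-of-ratios scaling, the culture as a block, libraries in place of cultures, only the groups compared, each culture and each library left out, a 2-fold minimum and the estimated correlation. Chosen after the data were seen were the shallow library left out, the same with scaling, and limma-voom on the recovered reads summed per culture. Other splits of the libraries were tested too, 35 for each pair of groups and 100 draws for comparisons over several days. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.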

Results

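Organoids grown from single cells of the mouse intestine were treated with all-trans retinoic acid or with an antagonist of the retinoid X receptors over their first days of growth. Organoids are self-organising epithelial cultures in which intestinal stem cells give rise to absorptive enterocytes and to secretory Paneth, goblet, enteroendocrine and tuft cells. Cultures from 2 male C57BL/6 littermates were given the vehicle DMSO, 10 µM all-trans retinoic acid (atRA, the ligand of the retinoic acid receptors) or 5 µM of the antagonist (RXRi). Retinoid X receptors are the shared partners of the retinoic acid, PPAR, LXR, FXR and vitamin D receptors. Messenger RNA was sequenced on days 1, 3, 4 and 5, given in the design text as 24, 72, 96 and 120 hours, and in a DMSO group on day 0. Treatment began on day 0 and was repeated on day 3, when the Wnt3a-conditioned medium, the ROCK inhibitor Y-27632 and the GSK3 inhibitor CHIR99021 were withdrawn. The 13 groups each held 2 cultures with RNA purified in duplicate, 52 libraries in all.

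Of 24116 genes, 19708 were above 0 in at least 1 library. Their values were whole multiples of the worth of 1 read, which gave the depth of each library. In 51 libraries there were 12895667 to 26206028 reads (median 19686970) and 14387 to 15800 genes above 0. The remaining library, duplicate 2 of culture 1 in the day 1 DMSO group, held 12443 reads and 5161 genes above 0. In it, 3 reads in a 1 kb gene amount to 241 RPKM, against 0.23 RPKM in the next shallowest. This shallow library was kept in the planned comparisons and enters the day 1 DMSO mean, so results are given also without it, an alternative chosen after the data were seen. A mixture of culture profiles, fitted afterwards, gave 73.6% of the reads in this library to days other than day 1. Where day 1 is not compared, leaving it out changes no fold change and lowers only the spread shared between the groups.

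**Figure D1:**
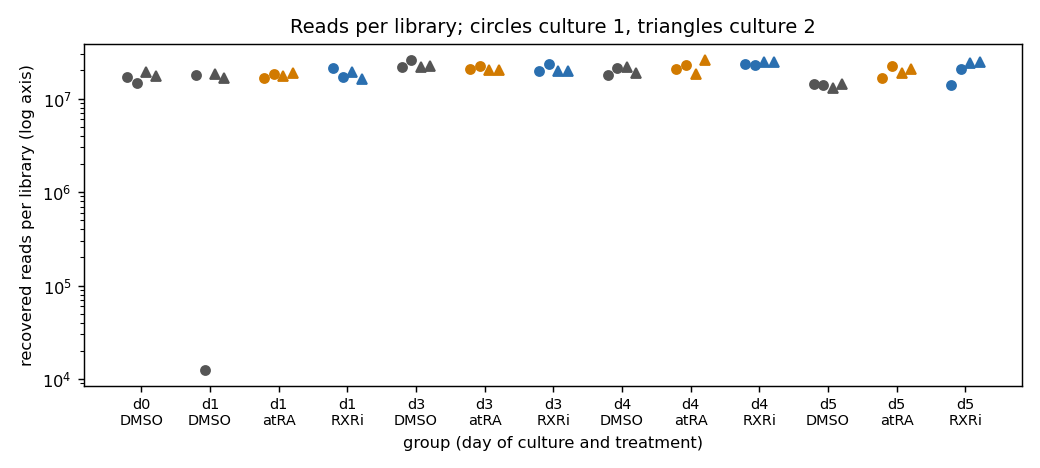
Reads per library on a log axis for the 13 groups, with 1 point per library (circles, culture 1; triangles, culture 2). A single day 1 DMSO library lies at 12443 reads, and the others lie between 12895667 and 26206028.

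**Figure D2:**
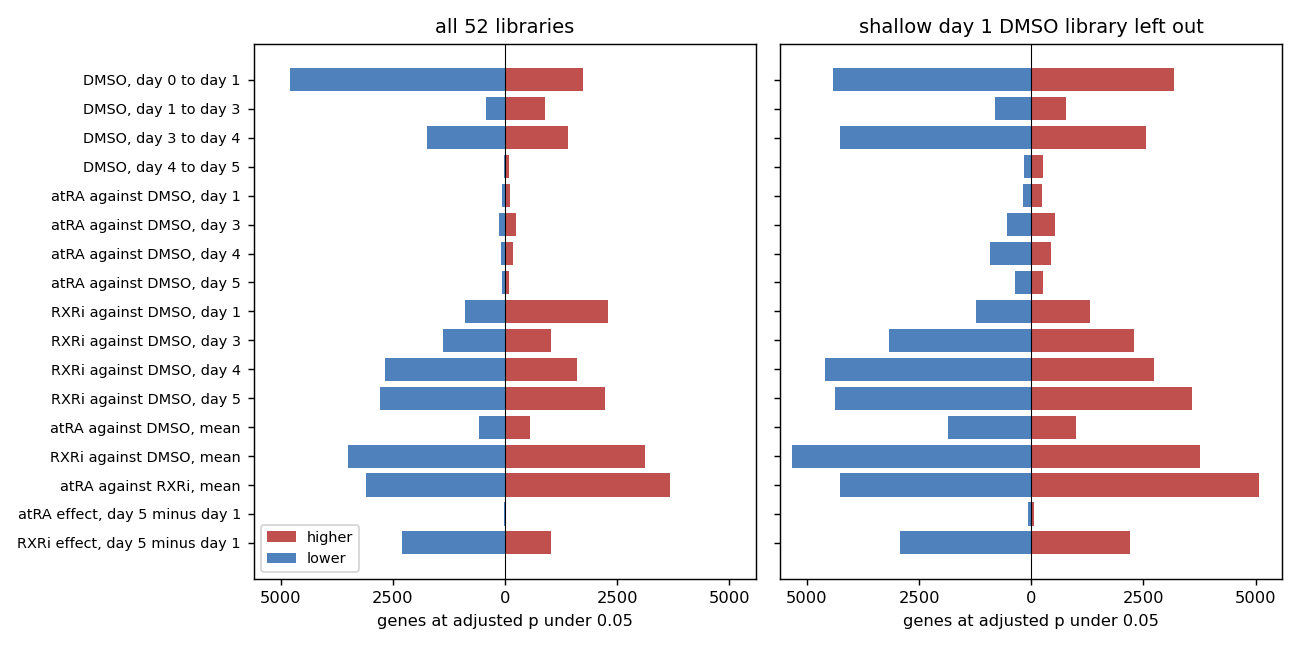
Genes past the test for each comparison (bars to the right, higher; to the left, lower), with all libraries and with the shallow library left out. With all libraries RXRi changed 3186 genes on day 1 and 5003 on day 5, and atRA 153 on day 5 to 378 on day 3.

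Over the first day after seeding, DMSO organoids gained markers of fetal-like and regenerating epithelium. On day 1, 16 of 17 measured genes of this list rose (16 adjusted over the list alone), by a mean log2 fold change of 3.13. Mesothelin (Msln) rose by 5.74 ± 0.36 (SE) from 4.49 ± 0.332 to 305 ± 103 RPKM (SD, n = 2 cultures), clusterin (Clu) by 4.64 ± 0.28 and the annexin Anxa8 by 4.60 ± 0.33. Ly6a, which encodes Sca-1, rose by 5.67 ± 0.49, S100a6 by 5.52 ± 0.40, Lgals3 by 5.14 ± 0.58 and Il1rn by 5.05 ± 0.63. Of the stem cell markers, 1 of 15 measured genes rose and 11 fell (1 and 11 adjusted over the list alone), including Aqp4 (-2.75 ± 0.24), Tnfrsf19 (-2.66 ± 0.24) and Rgmb (-2.21 ± 0.22). The falls of Olfm4 (-5.81 ± 0.74), Reg3b (-5.39 ± 0.48), Cyp2c68 (-4.61 ± 0.36), Pla2g1b (-4.56 ± 0.16) and Pipox (-4.30 ± 0.32) led the comparison; Olfm4 marks stem cells and Reg3b is an antimicrobial lectin. Olfm4 stood at -7.19 and Pipox at -3.57 without the shallow library, and without its duplicate instead at -4.44 and -5.03. In total 1737 genes were higher and 4796 lower on day 1, and 3188 and 4429 without the shallow library, which moved the median gene from -0.45 to -0.09. With median-of-ratios scaling as well the counts were 3805 and 3823. The list test gave adjusted p = 6.4e-16 (adjusted p = 0.42 with an estimated correlation) for the fetal-like genes, and adjusted p = 0.0052 (adjusted p = 0.465 with an estimated correlation) for the stem cell markers, a call lost without the duplicate of the shallow library (adjusted p = 0.059).

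Between days 1 and 3 the hormone genes of enteroendocrine cells fell. In that list 23 of 26 measured genes fell (26 adjusted over the list alone), by a mean log2 of -2.68 (-3.03 without the shallow library). Ghrelin (Ghrl) changed by -4.38 ± 0.27, the chromogranins Chga by -4.34 ± 0.19 and Chgb by -4.32 ± 0.32, proglucagon (Gcg) by -4.30 ± 0.37 and cholecystokinin (Cck) by -4.22 ± 0.35, the largest falls among the genes named. In lipid synthesis, 11 of 25 measured cholesterol genes rose (12 adjusted over the list alone), such as Nsdhl (0.78 ± 0.11) and Mvd (0.77 ± 0.14), and 6 of 15 measured fatty acid genes rose (9 adjusted over the list alone), such as Scd2 (1.10 ± 0.18) and Elovl6 (0.74 ± 0.14). Of Paneth cell genes, 5 of 17 measured genes fell (8 adjusted over the list alone), including Habp2 (-2.48 ± 0.30) and Itln1 (-1.18 ± 0.21). With the shallow library left out, 19 cholesterol and 10 fatty acid genes rose and 12 Paneth genes fell, with Habp2 at -1.65. The rises of Isx (4.20 ± 0.63), Dmbt1 (3.19 ± 0.57) and Selenbp1 (2.88 ± 0.61) were among the largest. Isx, a repressor of intestinal vitamin A uptake, stood at 6.04 without the shallow library (adjusted p = 1.6e-14), Selenbp1 at 2.27 (adjusted p = 0.01) and Dmbt1 at 4.46. The enteroendocrine list gave adjusted p = 2.8e-38 (adjusted p = 0.039 with an estimated correlation). The same test gave adjusted p = 0.0011 and 0.014 for the lipid lists and 3.2e-06 for the Paneth list, and with an estimated correlation adjusted p = 0.559, 0.257 and 0.541. Without the shallow library the lipid lists gave adjusted p = 0.036 and 0.0074 with an estimated correlation. Counts were 898 higher and 418 lower genes, and 770 and 807 without the shallow library. With scaling as well they were 794 and 778. Leaving out its duplicate instead gave 288 genes and ended the calls of Isx (2.36), Dmbt1 (1.93), Scd2 (0.89) and the lipid lists (adjusted p = 0.253 and 0.635), with Habp2 at -3.32 and Selenbp1 at 3.50.

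From day 3 to day 4, after the Wnt3a medium and the GSK3 inhibitor were withdrawn, absorptive genes rose. Of the enterocyte markers 32 of 34 measured genes rose (32 adjusted over the list alone), by a mean log2 of 2.98. Sucrase-isomaltase (Sis) rose by 5.46 ± 0.26, intestinal alkaline phosphatase (Alpi; Entrez gene 76768, chromosome 1, 87098002 to 87101606) by 4.82 ± 0.25, and the apolipoprotein genes Apoa4 by 6.62 ± 0.62 and Apoa1 by 6.18 ± 0.41. Apoa1 went from 5.14 ± 0.194 to 433 ± 2.89 RPKM (SD, n = 2 cultures). Reg1 (6.39 ± 0.44), Adh1 (6.17 ± 0.37) and Arg2 (5.75 ± 0.40) rose by similar amounts. Other lists moved with them: 18 of 24 measured brush border and transport genes rose (20 adjusted over the list alone), and 15 of 24 measured PPAR targets rose (17 adjusted over the list alone). In retinoid metabolism 12 of 21 measured genes rose and 1 fell (13 and 1 adjusted over the list alone), including the retinol dehydrogenase Rdh7 (4.24 ± 0.32) and the retinol-binding protein Rbp2 (5.16 ± 0.44). Of goblet cell genes 11 of 18 measured genes rose (13 adjusted over the list alone), including Zg16 (4.17 ± 0.25) and Agr2 (1.41 ± 0.16). Falling groups were proliferation, in which 23 of 30 measured genes fell (26 adjusted over the list alone), such as the replication helicase genes Mcm6 (-1.23 ± 0.18) and Mcm2 (-1.42 ± 0.21), and Wnt targets, in which 8 of 13 measured genes fell (9 adjusted over the list alone), such as Axin2 (-1.13 ± 0.23) and Cd44 (-1.51 ± 0.25).

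On day 4, 1398 genes were higher and 1745 lower than on day 3, and 2557 and 4273 without the shallow library. The list test gave adjusted p = 1.4e-32 for enterocyte, 6.5e-15 for brush border, 3.7e-11 for PPAR, 1.2e-09 for retinoid metabolism, 7.2e-09 for goblet, 3.7e-11 for proliferation and 2.7e-04 for Wnt genes. The calls for proliferation (adjusted p = 0.249 with an estimated correlation) and Wnt targets (adjusted p = 0.292 with an estimated correlation) were lost, and the other 5 held at adjusted p = 0.0041, 0.0041, 0.0041, 4.7e-04 and 0.045. With the shallow library left out, the goblet call was lost too (adjusted p = 0.192 with an estimated correlation). The median gene moved by -0.10 as deposited and by 0.02 after median-of-ratios scaling, which gave 1918 higher and 1214 lower genes, and 3445 and 3176 without the shallow library. Tubb6 (-2.13 ± 0.39) and the small nucleolar RNA genes Snord52 (-2.44 ± 0.61) and Snora61 (-2.26 ± 0.52) had large falls. These short RNAs overlap their host genes, so their values are uncertain.

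Absorptive genes rose further between days 4 and 5. Of the enterocyte genes 9 of 34 measured genes rose (21 adjusted over the list alone), by a mean log2 of 1.17, with apolipoprotein C3 (Apoc3) at 2.83 ± 0.37, Sis at 1.85 ± 0.26 and the glucose transporter Slc2a2 at 2.11 ± 0.32. Of the PPAR targets 2 of 24 measured genes rose (5 adjusted over the list alone), including Cd36 (1.67 ± 0.25). Reg1 (3.35 ± 0.44), Bst1 (2.90 ± 0.25) and Spink1 (2.81 ± 0.55) rose too, and Fkbp5 (-1.18 ± 0.22) fell. Of the Paneth cell genes 0 of 17 measured genes passed the limma test singly (5 higher and 0 lower adjusted over the list alone, and 8 higher and 0 lower at an unadjusted p under 0.05), with a mean log2 of 0.84. Without the shallow library 17 enterocyte, 6 PPAR and 6 Paneth genes rose. The enterocyte list gave adjusted p = 1.8e-46 (adjusted p = 0.0026 with an estimated correlation), the PPAR list adjusted p = 2.8e-13 (adjusted p = 0.0042 with an estimated correlation), which became adjusted p = 0.055 with an estimated correlation once the shallow library was left out, and the Paneth list adjusted p = 1.3e-15 (adjusted p = 0.058 with an estimated correlation). Counts were 94 higher and 11 lower genes, and 262 and 166 without the shallow library; with scaling as well they were 349 and 70.

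Over the 4 days together, atRA raised targets of PPAR, a fatty acid-sensing receptor, and of FXR, a bile acid receptor. Of the PPAR targets 23 of 24 measured genes rose (23 adjusted over the list alone), by a mean log2 of 1.65. They included liver fatty acid-binding protein (Fabp1; Entrez gene 14080, chromosome 6, 71199879 to 71205034) at 3.94 ± 0.23, pyruvate dehydrogenase kinase 4 (Pdk4) at 3.71 ± 0.15, the fatty acid hydroxylase Cyp4a10 at 3.48 ± 0.07 and the thioesterases Acot2 (2.69 ± 0.19) and Acot1 (2.39 ± 0.15). Cyp4a and Acot genes have close copies with which reads can be shared, so their single values are uncertain. Of the FXR targets 5 of 6 measured genes rose (5 and 1 lower adjusted over the list alone): the bile acid transporter subunits Slc51b (2.89 ± 0.14) and Slc51a (1.53 ± 0.15), the ileal bile acid-binding protein Fabp6 (3.15 ± 0.16), and the enterokine Fgf15 (2.83 ± 0.35) were among them. Of the LXR list 7 of 13 measured genes rose and 1 fell (7 and 1 adjusted over the list alone), including the sterol transporters Abcg5 (1.12 ± 0.15) and Abcg8 (0.94 ± 0.13), and of the fatty acid synthesis list 6 of 15 measured genes rose (7 adjusted over the list alone), including Acacb (2.13 ± 0.09) and Me1 (1.29 ± 0.13). The list test gave adjusted p = 3.4e-42 (adjusted p = 1.7e-05 with an estimated correlation) for PPAR and adjusted p = 6.2e-09 (adjusted p = 5.5e-04 with an estimated correlation) for FXR targets. For LXR it gave adjusted p = 2.5e-05 (adjusted p = 0.032 with an estimated correlation), and for fatty acid synthesis adjusted p = 1.4e-05 (adjusted p = 0.012 with an estimated correlation).

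Absorptive and goblet cell genes were also higher with atRA. Of the enterocyte genes 20 of 34 measured genes rose (25 adjusted over the list alone), by a mean log2 of 0.75, such as Creb3l3 (1.71 ± 0.19), Mep1b (1.52 ± 0.17) and Mttp (0.94 ± 0.11). Of the goblet genes 11 of 18 measured genes rose and 1 fell (13 and 1 adjusted over the list alone), with the mucus-processing protease gene Clca1 at 3.00 ± 0.21 and S100a6 at -1.75 ± 0.20. In retinoid metabolism 8 of 21 measured genes rose and 1 fell (11 and 2 adjusted over the list alone), including Retsat (1.69 ± 0.23), Rbp2 (1.29 ± 0.22) and Adh1 (1.06 ± 0.18), the last at 0.89 and not past the test (adjusted p = 0.096) without the duplicate of the shallow library. On the other side, 10 of 17 measured fetal-like and regeneration genes fell (11 adjusted over the list alone), including Anxa8 (-2.19 ± 0.17), Msln (-1.50 ± 0.18) and Clu (-1.03 ± 0.14), and 6 of 18 measured YAP targets fell (6 adjusted over the list alone), including F3 (-1.66 ± 0.30), Myof (-1.11 ± 0.18) and Ankrd1 (-1.09 ± 0.17). With the shallow library left out, 10 YAP targets fell. The collagen IV genes Col4a2 (-2.09 ± 0.13) and Col4a1 (-1.97 ± 0.16), which lie side by side and code for basement membrane chains, and Anxa1 (-1.84 ± 0.26), Cnfn (-1.81 ± 0.15), Cav2 (-1.80 ± 0.18), Cwh43 (-1.74 ± 0.20) and Gcnt1 (-1.63 ± 0.23) fell as well. The list test gave adjusted p = 9.4e-16 for enterocyte, 1.1e-08 for goblet, 0.0012 for retinoid metabolism, 1.8e-09 for fetal-like and 4.9e-05 for YAP genes. The last calls were lost (adjusted p = 0.164 and adjusted p = 0.283 with an estimated correlation), and the first held at 0.036, 0.046 and 0.024, with goblet at 0.055 without the shallow library.

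Counts for atRA over the 4 days were 555 higher and 579 lower genes, and 993 and 1861 without the shallow library. With median-of-ratios scaling they were 728 and 418, and 1301 and 1250 with both changes. Leaving out the duplicate of the shallow library instead gave 517 genes. A change of at least 2-fold was found in 111 higher genes, Fabp1 first, and 58 lower genes, Anxa8 first.

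By day, atRA effects on single genes differed in size. On day 1 the largest rises among the genes named were those of Isx (4.79 ± 0.63), Dhrs3 (3.79 ± 0.24) and Fabp1 (3.79 ± 0.47), and large falls were those of Anxa8 (-2.50 ± 0.33) and Cwh43 (-2.15 ± 0.41). Dhrs3 encodes a retinaldehyde reductase. Isx and Fabp1 stood at 6.63 and 5.02 without the shallow library. Leaving out its duplicate instead ended the calls of Isx (2.95), Fabp1 (2.57) and Cwh43 (-2.73). On day 3 large rises were those of Fabp1 (7.12 ± 0.47) and Ces1f (3.97 ± 0.28), against Cnfn (-3.14 ± 0.31), Wfdc2 (-2.92 ± 0.39) and Col4a1 (-2.55 ± 0.33), and 19 of 34 measured enterocyte genes rose (26 adjusted over the list alone), by a mean log2 of 1.71. On day 4 they were those of Fabp6 (6.12 ± 0.33) and Cyp4a10 (4.59 ± 0.14), against Wfdc2 (-3.24 ± 0.39) and Ctrb1 (-2.60 ± 0.48), and 7 of 34 measured enterocyte genes rose (21 adjusted over the list alone), with a mean of 1.00, 15 of them without the shallow library. On day 5 Cyp4a10 (5.67 ± 0.14), Fabp6 (5.37 ± 0.33) and the retinoic acid hydroxylase Cyp26b1 (5.29 ± 0.35; Entrez gene 232174, chromosome 6, 84571414 to 84593908) led, against Ctrb1 (-4.54 ± 0.48), Akr1c14 (-2.86 ± 0.26) and Wfdc2 (-2.59 ± 0.39). Cyp26b1 stood at 82.7 ± 57.1 RPKM with atRA and 0.892 ± 0.378 with DMSO (SD, n = 2 cultures). On that day 0 of 34 measured enterocyte genes passed the limma test singly (0 higher and 0 lower adjusted over the list alone, and 4 higher and 3 lower at an unadjusted p under 0.05), with a mean of 0.05, a median of -0.03 and adjusted p = 0.89 (adjusted p = 0.954 with an estimated correlation), and 3 were higher and 1 lower without the shallow library. The 2 atRA cultures of that day differed more than those of any other group, with chi-square per degree of freedom of 78.9 to 102. Apoa4 with atRA, for example, stood at 2525 ± 2290 RPKM (SD, n = 2 cultures). A mean near 0 thus does not show that the effect was absent.

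Counts by day were 125 higher and 53 lower on day 1, 245 and 133 on day 3, 173 and 90 on day 4, and 98 and 55 on day 5. Without the shallow library they were 240 and 191, 538 and 542, 446 and 915, and 266 and 360, and with scaling as well 540 and 479 on day 3. Leaving out its duplicate instead gave 37 genes on day 1. PPAR targets stood at a mean log2 of 1.16, 2.00, 1.90 and 1.54 on the 4 days. On the first of these, 12 of 24 measured PPAR targets rose (19 and 1 lower adjusted over the list alone), where the list gave adjusted p = 8.7e-07 (adjusted p = 0.098 with an estimated correlation). With the shallow library left out, it gave adjusted p = 3.9e-36 (adjusted p = 0.0017 with an estimated correlation). For enterocyte genes on days 3 and 4 it gave adjusted p = 1.3e-48 (adjusted p = 7.1e-04 with an estimated correlation) and adjusted p = 4.6e-32 (adjusted p = 0.0024 with an estimated correlation). On day 4 the median gene moved by -0.12 as deposited and by 0.01 with median-of-ratios scaling, which gave 253 higher and 71 lower genes, and 664 and 367 without the shallow library.

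**Figure D3:**
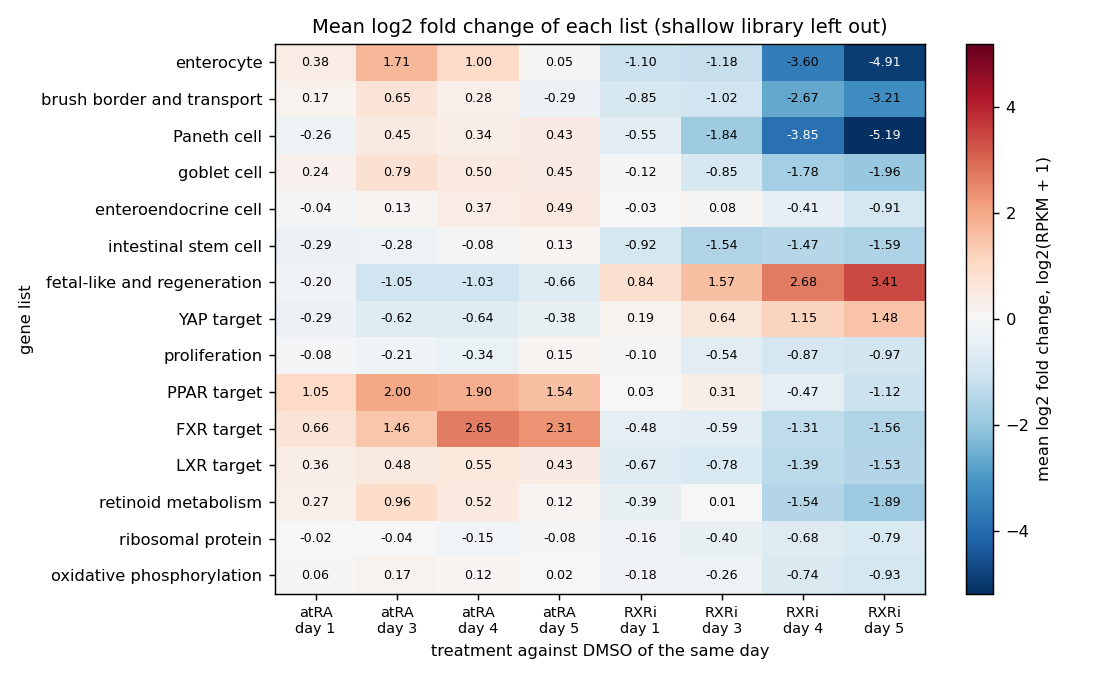
Mean log2 fold change of 15 gene lists (vertical) against DMSO of the same day (horizontal, atRA and RXRi on days 1, 3, 4 and 5), with the shallow library left out; red is higher and blue lower. Enterocyte genes stand at 1.71 with atRA on day 3 and at -4.91 with RXRi on day 5, and fetal-like genes at 3.41 with RXRi on day 5.

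The RXR antagonist lowered enterocyte and Paneth cell markers over the 4 days together. Of the enterocyte genes 1 of 34 measured genes rose and 32 fell (1 and 32 adjusted over the list alone), by a mean log2 of -2.74. Among the largest falls were the galectin gene Lgals2 (-7.56 ± 0.09), the urea cycle enzyme gene Cps1 (-6.86 ± 0.09; Entrez gene 227231, chromosome 1, 67122426 to 67231267), the immunoglobulin transporter Pigr (-6.20 ± 0.08), the tight junction gene Cldn15 (-6.12 ± 0.15), Alpi (-5.64 ± 0.12), Apoa1 (-5.50 ± 0.20) and Adh1 (-5.49 ± 0.18). Of brush border genes 23 of 24 measured genes fell (23 adjusted over the list alone), such as Myo1a (-3.10 ± 0.10) and Slc26a3 (-3.06 ± 0.12). All 17 measured Paneth cell genes fell (adjusted over the list alone, 17), by a mean of -2.72, with lysozyme (Lyz1) at -4.78 ± 0.15 and the lectin Itln1 at -4.41 ± 0.11. The defensins Defa3 (-5.07 ± 0.13) and Defa17 (-5.03 ± 0.14) belong to a family of near-identical copies, so their single values are uncertain. Of goblet genes 2 of 18 measured genes rose and 15 fell (2 and 15 adjusted over the list alone), with Muc13 (-5.43 ± 0.06) and Agr2 (-2.15 ± 0.08) lower and Sytl2 (2.23 ± 0.13) higher. Of stem cell markers 2 of 15 measured genes rose and 11 fell (2 and 11 adjusted over the list alone), including Smoc2 (-4.18 ± 0.11), Lgr5 (-2.88 ± 0.19) and Lrig1 (-1.53 ± 0.09).

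Fetal-like and regeneration genes rose with RXRi. In that list 16 of 17 measured genes rose (16 adjusted over the list alone), by a mean log2 of 2.12, including Anxa8 (3.48 ± 0.17), the growth factor gene Ereg (1.63 ± 0.07), Krt7 (2.32 ± 0.11) and Ly6e (1.83 ± 0.09). Of the YAP targets 14 of 18 measured genes rose and 1 fell (14 and 1 adjusted over the list alone), with Myof at 2.45 ± 0.18, Ajuba at 1.81 ± 0.15 and Nuak2 at -1.50 ± 0.14. Of the immediate early and heat shock genes 15 of 23 measured genes rose and 1 fell (16 and 1 adjusted over the list alone), such as Ier3 (2.42 ± 0.20), Klf4 (1.88 ± 0.20) and Hspb1 (1.08 ± 0.10). The largest rises were those of the trefoil factor gene Tff1 (6.65 ± 0.36; Entrez gene 21784, chromosome 17, 31161395 to 31165060), Mal (5.28 ± 0.17), Ly6d (4.88 ± 0.36), Trim29 (4.82 ± 0.10), Psca (3.93 ± 0.20), Cyp1b1 (3.85 ± 0.12), Krt79 (3.63 ± 0.09), Mcpt2 (3.62 ± 0.15), Prl2c3 (3.58 ± 0.51) and Lypd6b (3.55 ± 0.07). Tff1 stood at 4747 ± 334 RPKM with RXRi and 3.31 ± 1.26 with DMSO on day 5 (SD, n = 2 cultures). Mcpt2 and Prl2c3 belong to gene families with close copies, so their values are uncertain. Markers of other epithelia were examined beside this group on day 5. Of 11 stratified epithelium markers, 5 reached 1 RPKM with RXRi or DMSO, of which 5 were at least 2-fold higher with RXRi. Of 9 stomach markers, 4 did, of which 3 were at least 2-fold higher and 1 lower (Gkn3, 0.0129 and 3 RPKM). Apart from Krt4, these stratified epithelium markers (Krt13, Krt14, Krt15 and Dsg3) reached 1 RPKM with RXRi alone. The stomach markers Gkn1, Gkn2 and Muc5ac did so too, and Gkn3 reached it with DMSO alone. A marker that reaches it in a single group is higher there through this choice. Mean levels with RXRi and with DMSO were 119 and 8.9 RPKM for the stratified epithelium keratin gene Krt4, 28 and 0.022 RPKM for the stomach gene Gkn2, and 15.2 and 0.016 RPKM for the stomach gene Gkn1. The stratified epithelium regulator Trp63 was listed at 0 in both groups. The marker lists were written after the most changed genes had been seen, Krt4, Gkn2 and Gkn3 among them, and before the levels given here were read, and the genes printed were picked from them afterwards.

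Housekeeping groups were lower with RXRi. Of the ribosomal protein genes 42 of 45 measured genes fell (42 adjusted over the list alone), by a mean log2 of -0.46 and by -0.79 on day 5, such as Rpl5 (-0.73 ± 0.06) and Rps4x (-0.67 ± 0.06). Of the oxidative phosphorylation genes 22 of 30 measured genes fell (23 adjusted over the list alone), by a mean of -0.43, such as Sdha (-0.75 ± 0.04) and Sdhd (-0.90 ± 0.06), and of the proliferation genes 22 of 30 measured genes fell (22 adjusted over the list alone), such as Pcna (-0.93 ± 0.07) and Mcm7 (-0.85 ± 0.10). With median-of-ratios scaling and the shallow library left out, the ribosomal protein mean was -0.45 and the oxidative phosphorylation mean -0.47.

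With RXRi over the 4 days 3115 genes were higher and 3490 lower, and 3752 and 5330 without the shallow library. The list test gave adjusted p = 1.9e-16 for enterocyte, 1.2e-11 for brush border, 5.5e-10 for Paneth, 2.9e-05 for goblet, 2.5e-04 for stem cell, 4.8e-10 for fetal-like, 2.5e-04 for YAP, 3.3e-04 for immediate early, 9.6e-12 for ribosomal protein, 2.3e-07 for oxidative phosphorylation and 6.6e-05 for proliferation genes. None of these calls held with an estimated correlation: the same lists gave adjusted p = 0.069, 0.058, 0.153, 0.153, 0.171, 0.153, 0.368, 0.171, 0.171, 0.171 and 0.42. Median-of-ratios scaling with all libraries turned the balance to 3973 higher and 2982 lower genes, and without the shallow library it gave 4264 and 4890.

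On each of the 4 days Cps1 was lower with RXRi (-5.17 ± 0.17, -7.01 ± 0.17, -7.37 ± 0.17 and -7.90 ± 0.17) and Jdp2 higher (3.77 ± 0.37, 2.86 ± 0.37, 2.95 ± 0.37 and 3.36 ± 0.37). The stress gene Trib3 stood at 4.01 ± 0.67, 2.29 ± 0.67 (0.98 without culture 2 of day 3 DMSO, adjusted p = 0.407), 0.77 ± 0.67 (adjusted p = 0.432) and 1.54 ± 0.67 (adjusted p = 0.08, and 0.043 without the shallow library). Genes given below for a day had large effects on it and were not tested for being confined to it. On day 1 the amino acid stress genes Trib3 and Chac1 (3.89 ± 0.52) and Jdp2 rose most, and 9 of 21 measured genes of the unfolded protein and integrated stress response rose (10 adjusted over the list alone), including Atf4 (0.67 ± 0.11) and Psat1 (0.95 ± 0.16). Large day 1 falls were those of Cps1, Cyp2c55 (-4.84 ± 0.21) and Lypd8 (-4.44 ± 0.31). On day 3 Tff1 (6.40 ± 0.71), Mal (5.37 ± 0.34) and Trim29 (4.81 ± 0.20) led, against Lgals2 (-7.97 ± 0.19) and Pigr (-6.56 ± 0.16). On day 4 Tff1 (8.88 ± 0.71), Mal (6.73 ± 0.34) and involucrin (Ivl, 6.37 ± 0.62) led, against Lgals2 (-9.09 ± 0.19) and Adh1 (-8.27 ± 0.37). On day 5 Tff1 reached 10.15 ± 0.71, Mal 7.25 ± 0.34 and Mcpt2 6.59 ± 0.30, while large falls were those of Apoa1 (-9.65 ± 0.41) and Apoa4 (-9.51 ± 0.62). Apoa1 stood at 1.17 ± 0.163 RPKM with RXRi and 1719 ± 87.7 with DMSO on day 5 (SD, n = 2 cultures).

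On day 5, 1 of 34 measured enterocyte genes rose and 32 fell (1 and 32 adjusted over the list alone), by a mean log2 of -4.91, all 17 Paneth genes fell (adjusted over the list alone, 17), by -5.19, and all 17 fetal-like genes rose (adjusted over the list alone, 17), by 3.41. Counts on days 1, 3, 4 and 5 were 2302, 1029, 1617 and 2223 higher and 884, 1368, 2679 and 2780 lower genes. Without the shallow library they were 1303, 2292, 2740 and 3575 higher and 1235, 3166, 4600 and 4367 lower, and leaving out its duplicate instead gave 1502 genes on day 1. With median-of-ratios scaling day 3 turned to 1261 higher and 1128 lower genes (2557 and 2864 without the shallow library), and day 1 without the shallow library to 1117 and 1416. The shallow library moved the median gene of the day 1 comparison from -0.00 to 0.27. The stress list on day 1 gave adjusted p = 0.041 (adjusted p = 0.66 with an estimated correlation), and its call was lost also without the duplicate of the shallow library (adjusted p = 0.171) or without duplicate 1 of RXRi culture 2 (adjusted p = 0.052). On day 5 the enterocyte list gave adjusted p = 7.2e-21 (adjusted p = 0.038 with an estimated correlation), which became adjusted p = 0.235 with an estimated correlation once the shallow library was left out, the Paneth list adjusted p = 2.0e-12 (adjusted p = 0.108 with an estimated correlation), and the fetal-like list adjusted p = 6.8e-13 (adjusted p = 0.108 with an estimated correlation). On day 4 the median gene moved by -0.13 as deposited and by 0.02 with median-of-ratios scaling, which gave 2245 higher and 2169 lower genes, and 3651 and 3701 without the shallow library.

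**Figure D4:**
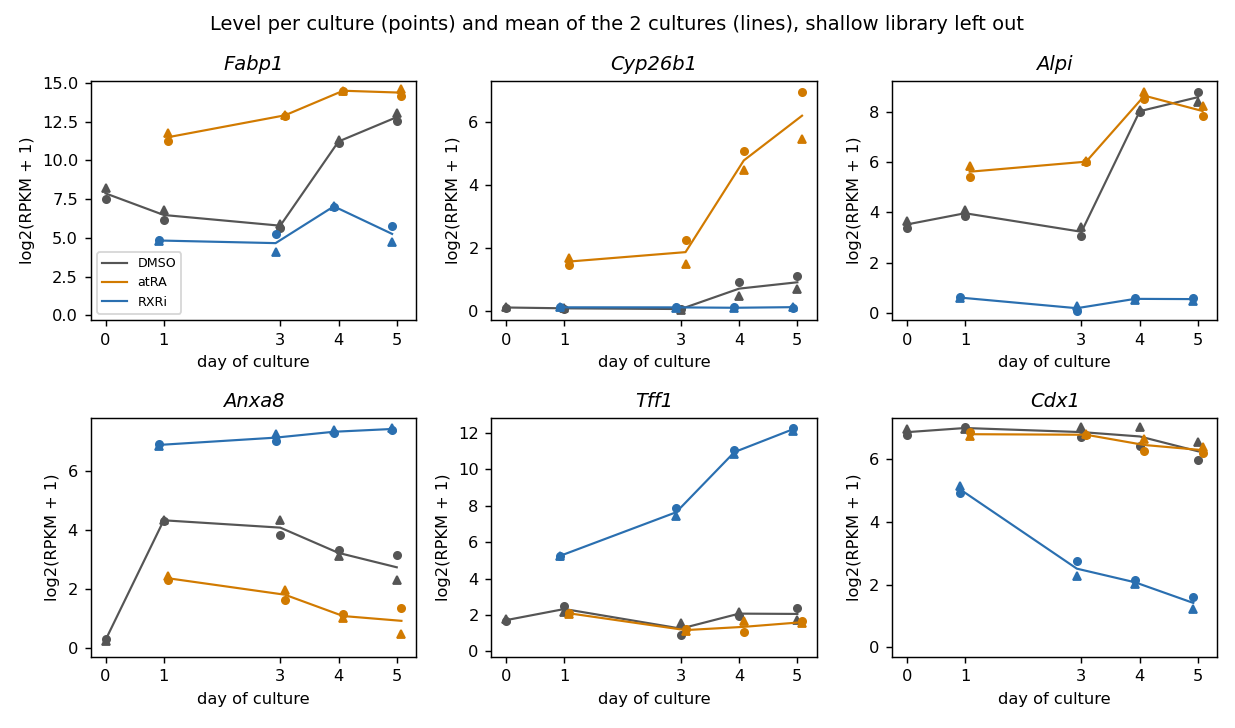
Level of 6 genes by day of culture, as log2(RPKM + 1), for DMSO, atRA and RXRi, with the shallow library left out; points are the 2 cultures and lines their mean. Against DMSO over the 4 days, Tff1 and Anxa8 lie higher with RXRi (7.08 and 3.61 without the shallow library) and Alpi and Cdx1 lower (-5.50 and -3.95), while Fabp1 and Cyp26b1 lie higher with atRA (4.25 and 3.16).

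Some genes known to be induced by retinoic acid rose with atRA and fell with RXRi. With atRA over the 4 days, 4 of 11 measured genes rose and 2 fell (5 and 2 adjusted over the list alone). Among them, Cyp26b1 (3.17 ± 0.17), Dhrs3 (1.90 ± 0.12), Isx (2.02 ± 0.31) and the transglutaminase gene Tgm2 (0.51 ± 0.11) rose, and Lrat (-0.19 ± 0.06) fell. Leaving out the duplicate of the shallow library ended the calls of Isx (1.56), Tgm2 (0.39) and Lrat (-0.17). This leaves the shallow library alone for its culture in the day 1 DMSO group. With the shallow library itself left out, these calls held, and Isx with atRA on day 1 stood at 6.63. The Lrat call was lost on leaving out any 1 of 8 DMSO or atRA libraries. With RXRi, 2 of 11 measured genes rose and 6 fell (2 and 6 adjusted over the list alone). Among them, Isx (-5.23 ± 0.31), the homeobox gene Cdx1 (-3.96 ± 0.12; Entrez gene 12590, chromosome 18, 61018862 to 61036199), Tgm2 (-3.70 ± 0.11), Dhrs3 (-2.53 ± 0.12), Stra6l (-1.23 ± 0.16) and Lrat (-0.45 ± 0.06) fell, and the receptor gene Rarg (1.5 ± 0.14) rose. Values not past the test were Cyp26b1 with RXRi (-0.33 ± 0.17, adjusted p = 0.132) and, with atRA, Cdx1 at -0.14 ± 0.12 (adjusted p = 0.501) and Rarg at -0.08 ± 0.14 (adjusted p = 0.748). Mean Cyp26b1 levels with DMSO were below 1 RPKM on all 4 days, so a fall could hardly show on this scale. On day 5 they were 0.892 RPKM with DMSO and 0.08 with RXRi. Among the other receptors, Rxra (-0.31 ± 0.07) and Rxrb (-0.51 ± 0.10) fell with RXRi, and Rara stood at -0.13 ± 0.15 (adjusted p = 0.489), and at -0.32 without the shallow library (adjusted p = 2.4e-05). With atRA none of these passed: Rara at 0.16 ± 0.15 (adjusted p = 0.53), Rxra at -0.15 ± 0.07 (adjusted p = 0.182) and Rxrb at -0.01 ± 0.10 (adjusted p = 0.96). Rarb and Rxrg were below the RPKM minimum and not tested. With atRA the list gave adjusted p = 0.0082 (adjusted p = 0.085 with an estimated correlation), and with RXRi adjusted p = 0.025 (adjusted p = 0.153 with an estimated correlation). With the shallow library left out, the RXRi call was lost (adjusted p = 0.062, and 0.345 with an estimated correlation). By day, its mean log2 with atRA was 1.10, 0.44, 0.49 and 0.69 (median 0.57, 0.11, 0.00 and 0.06), and with RXRi -0.28, -1.47, -1.59 and -1.69 (median 0.10, -0.51, -0.62 and -0.79), so mean and median differ in sign with RXRi on day 1. The day 1 list test with atRA gave adjusted p = 0.193 (0.73 with an estimated correlation), and 2.1e-04 without the shallow library (0.056 with an estimated correlation).

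Set directly against each other over the 4 days, atRA and RXRi differed in 6791 genes, 3689 higher and 3102 lower with atRA. Higher with atRA were Fabp1 (7.87 ± 0.23), Cps1 (7.36 ± 0.09), Isx (7.25 ± 0.31), Pigr (7.24 ± 0.08) and Lgals2 (7.05 ± 0.09), and lower were Tff1 (-7.46 ± 0.36), Mal (-6.21 ± 0.17), Ly6d (-6.09 ± 0.36), Anxa8 (-5.66 ± 0.17) and Cnfn (-5.24 ± 0.15). Among enterocyte genes 32 of 34 measured genes were higher with atRA and 1 was lower (32 and 1 adjusted over the list alone), and the mean difference was 3.48. Among PPAR targets 20 of 24 measured genes were higher and 1 was lower (20 and 2 adjusted over the list alone), with a mean of 1.94, and among fetal-like genes 16 of 17 measured genes were lower (17 adjusted over the list alone), with a mean of -2.86. The enterocyte list gave adjusted p = 2.9e-17 (adjusted p = 0.025 with an estimated correlation), the PPAR list adjusted p = 7.7e-09 (adjusted p = 0.025 with an estimated correlation), and the fetal-like list adjusted p = 3.2e-11 (adjusted p = 0.106 with an estimated correlation). With the shallow library left out, the counts were 5072 and 4266, and the enterocyte and PPAR calls were lost (adjusted p = 0.171 for each with an estimated correlation). The drugs differ in target and dose, 10 and 5 µM.

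Genes called under both drugs over the 4 days together mostly had opposite signs. In this comparison 386 genes were higher with atRA and lower with RXRi, against 156 for independent lists of these sizes, and 368 were lower with atRA and higher with RXRi, against 145. The same direction was shared by 71 higher and 124 lower genes, against 139 and 162. These numbers were 713, 1068, 154 and 480, against 425, 561, 299 and 797, without the shallow library. On day 1 alone, 30 and 12 genes had opposite signs, against 8.9 and 9.8 for independent lists. The same sign was shared by 20 and 20, against 23.1 and 3.8. Without the shallow library they were 98 and 78, against 23.8 and 20, and 28 and 42, against 25.1 and 19. On day 5, 62 and 23 had opposite signs, against 21.9 and 9.8, and 8 and 22 the same, against 17.5 and 12.3. Without the shallow library they were 162 and 133, against 93.3 and 103, and 48 and 171, against 76.4 and 126. Genes lower with atRA on day 5 were thus not clearly opposite with RXRi. Across the 12445 genes, which are not independent replicates, Pearson's r between the atRA and RXRi fold changes was 0.654, -0.285, -0.364 and -0.134 on days 1, 3, 4 and 5. Both drugs share the DMSO libraries, and unchanged groups simulated against them gave r = 0.963, 0.443, 0.579 and 0.695. The simulated drug groups were given a spread shared over all groups. The day 5 atRA cultures differed more than those of any other group, so the simulated r of that day may be too high. The covariance minus the simulated one was -0.138, -0.091, -0.164 and -0.091. With the DMSO cultures divided between the drugs, r was -0.039 and -0.117 on day 1, -0.302 and -0.326 on day 3, -0.453 and -0.301 on day 4, and -0.312 and 0 on day 5. Without the shallow library the day 1 value turned to -0.11, against 0.337 simulated.

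Whether a drug effect changed with time was tested as the effect on day 5 minus that on day 1. For atRA, Fabp6 (5.43 ± 0.46), Cyp4a10 (5.30 ± 0.20), Cyp26b1 (3.79 ± 0.49) and the calcium-binding protein gene S100g (3.66 ± 0.42) had higher effects on day 5, and Ctrb1 (-5.23 ± 0.68), Dhrs3 (-2.94 ± 0.34) and Akr1c14 (-2.94 ± 0.37) lower ones. The lower ones rest mainly on a rise with DMSO. From day 1 to day 5, Dhrs3 went from 0.942 to 49 RPKM with DMSO, and from 24.5 to 89 with atRA. Ctrb1 went from 5.12 to 107 RPKM with DMSO and from 6.67 to 3.26 with atRA. Akr1c14 went from 1.5 to 31.5 and from 1.4 to 3.5. For RXRi, Tff1 (8.96 ± 1.01), Ivl (7.07 ± 0.87) and Mcpt2 (6.32 ± 0.43) had higher effects on day 5, and Reg1 (-9.86 ± 0.63), Apoa4 (-9.49 ± 0.88) and the defensin Defa30 (-9.38 ± 1.21) lower ones. Reg1 stood at 0.518 RPKM with DMSO and 1.15 with RXRi on day 1, and at 1360 and 1.10 on day 5. Apoa4 went from 13 to 1606 RPKM with DMSO, and from 7.78 to 1.16 with RXRi. The differences for Reg1 and Apoa4 thus rest mainly on a rise with DMSO that the RXRi cultures lacked. In total 30 genes had an atRA effect and 3322 an RXRi effect that differed between the days, and 143 and 5144 without the shallow library. Leaving out its duplicate instead gave 1919 genes for RXRi. Values without the shallow library were -4.51 for Ctrb1, 7.23 for Tff1, 5.58 for Ivl, -8.51 for Apoa4 and -7.19 for Defa30, and without its duplicate -5.94, 10.69, 8.55, -10.47 and -11.58. Both comparisons include the day 1 DMSO group.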

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

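The shallow library's mixture tests, the test of reads from other libraries and the counts of markers at 0 by cell type were chosen only after the result was seen; the other tests of explanations in this part were written before their values were computed, when the most changed genes had been seen. In 4 of 39 tests of a measure within a group of 4 libraries, a library stood apart from the rest by more than Dixon's 95% critical value, and chance gives about 1 in 20. They were the 12443 reads of the shallow day 1 DMSO library (the other 3 held 16758689 to 18533783) and its 5161 genes above 0. In culture 1 of the day 3 RXRi group, duplicate 2 held 23326228 reads against 19582897 to 19867465, and in culture 1 of the day 3 DMSO group the 10 most abundant genes took 4.36% of the reads of duplicate 2 against 3.97 to 4.03%.

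Drug effects differed between day 5 and day 1 by limma's test of the difference in 30 genes for atRA and 3322 for RXRi. For atRA the day 5 effect minus the day 1 effect was, in log2 units, 5.43 for Fabp6, 5.30 for Cyp4a10, 3.79 for Cyp26b1, 3.71 for Cyp4a32 and 3.66 for S100g. Such a difference does not tell a larger effect from one that changed sign. The difference was negative for Ctrb1 (-5.23), Dhrs3 (-2.94), Akr1c14 (-2.94), Wfdc2 (-2.81) and Aldh3a1 (-2.35). For RXRi it was 8.96 for Tff1, 7.07 for Ivl, 6.32 for Mcpt2, 5.50 for Mal and 5.02 for Psca, and -9.86 for Reg1, -9.49 for Apoa4, -9.38 for Defa30, -8.02 for Defa17 and -7.97 for Defa3. The Reg1 and Apoa4 values for RXRi, and the Ctrb1, Dhrs3 and Akr1c14 values for atRA, rest mainly on a rise with DMSO, as given in the results. Values without the shallow library, and without its duplicate instead, were -4.51 and -5.94 for Ctrb1, -1.94 and -3.68 for Wfdc2, 7.23 and 10.69 for Tff1, 5.58 and 8.55 for Ivl, 4.48 and 6.51 for Mal, 5.67 and 4.36 for Psca, -8.51 and -10.47 for Apoa4, and -7.19 and -11.58 for Defa30. The Wfdc2 call was lost on leaving out any 1 of 7 DMSO or atRA libraries of days 1 and 5.

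The shallow library in the day 1 DMSO group was set against 3 explanations. Low depth alone was left undecided by the planned test, with 5161 genes above 0 against 4960 to 5147 in 100 thinned draws of its duplicate, but a mixture of culture profiles gave 73.6% of its reads to days other than day 1, against 0.6 to 9.8% in 11 day 1 libraries thinned alike. The planned log-likelihood test, at -175, by itself went toward a library of another group, yet no single profile accounted for it, since the mixture gained 692 in log-likelihood over the best one, against -3.9 to 18.4 in the thinned libraries. Reads of many other libraries assigned to it remain a candidate explanation: 21 of 26 profiles each took over 1% of its reads, against 3 to 8, and its own group took 8.9%. No biological explanation was tested.

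Ribosomal protein genes stood at a mean log2 of -0.79 with RXRi on day 5. The tables argue against a few abundant genes taking more of the reads as the whole cause. With totals taken without the 100 most abundant genes, the mean of the 39 ribosomal protein genes outside these went from -0.79 to -0.73. Loss of short transcripts cannot be told apart from a change of the genes themselves, since other genes matched on length and level had a median of -0.33, between 0 and the list's -0.80. An effect of the RXR antagonist on these genes stays open as well.

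The genes higher with RXRi on day 5 might come from organoids held at an earlier day or from cells of another type. The tables argue against a delay along the sampled DMSO days for the whole pattern. Of the genes called higher, 37.4% (831 of 2223) lay above every DMSO day by at least 1.5-fold in both cultures. Without the shallow library the share was 25.8%, which is close to the bound set beforehand. A DMSO peak between the sampled days would not be seen in this test. Cells of another type were left undecided as a whole by the planned test, whose highest marker, Krt4 of stratified epithelium, reached 136 RPKM in a library, between the bounds set beforehand. Stomach markers were left out of this test and of the counts by type, so stomach cells were not put to a test. Of 4 stomach markers that reached 1 RPKM with RXRi or DMSO, 3 were at least 2-fold higher with RXRi and 1 was lower. Each of these 4 reached 1 RPKM in a single group, so its direction follows from that choice. By type, the tables argue against mast cells (4 of 8 markers at 0 in every RXRi day 5 library), placenta (3 of 7) and fibroblasts (4 of 8), such as Cpa3, Tpbpa and Col1a2, with median highest values of 0.018, 0.041 and 0.025 RPKM, although Mcpt4 reached 5.25 RPKM, while the strongest named higher gene stood at 4747 RPKM. Stratified epithelium (1 of 11 markers at 0, median 0.998 RPKM) cannot be told apart from a change within the epithelium. All 5 of its markers that reached 1 RPKM with RXRi or DMSO were at least 2-fold higher with RXRi. Of these, Krt4 alone reached 1 RPKM with DMSO too, so for the others the direction follows from that choice. Against stratified epithelium, Trp63 was at 0, and Krt5 stood at 0.66 RPKM with RXRi and 0.57 with DMSO. Its markers other than Krt4 stayed at or below 4.67 RPKM. A response of epithelial cells to RXRi stays open.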

How the results depend on the processing

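The shallow library left out, the same with scaling and limma-voom were chosen only after the results were seen, and the other alternatives before. Counts of genes that moved by over 1.5 times are given here, and the cause was not tested unless stated. With a pseudocount of 0.1 they were 645 (DMSO day 1 to 3), 22 (DMSO day 4 to 5), 91 (atRA day 1), 162 (atRA day 4), 101 (atRA day 5) and 16 (the atRA change with time), and without the filter on low values 241 (atRA day 5) and 46 (the atRA change with time). With libraries in place of cultures, which counts duplicates as replicates, they were 5164 (DMSO day 1 to 3), 658 (DMSO day 4 to 5), 3812 (atRA day 1), 928 (atRA day 3), 1312 (atRA day 4), 635 (atRA day 5), 6168 (RXRi day 1), 3794 (RXRi day 3), 2563 (the atRA mean), 446 (the atRA change with time) and 5026 (the RXRi change with time). With only the groups compared in the fit, which leaves few residual degrees of freedom, they were 37 (DMSO day 0 to 1), 3 (DMSO day 1 to 3), 5457 (DMSO day 3 to 4), 0 (DMSO day 4 to 5), 0 (atRA day 1), 1375 (atRA day 3), 7 (atRA day 5), 2 (RXRi day 1), 6474 (RXRi day 3), 6665 (RXRi day 4), 481 (the atRA mean), 2 (the atRA change with time) and 766 (the RXRi change with time). Where limma called 0, 806 genes between days 4 and 5 and 255 genes with atRA on day 1 had an unadjusted p under 0.05. Chance alone gives a share of 0.05 of the 12445 genes, which is more than 255 and less than 806. A 2-fold minimum, which removes smaller changes, gave 3324 (DMSO day 0 to 1), 665 (DMSO day 1 to 3), 1108 (DMSO day 3 to 4), 164 (atRA day 4), 90 (atRA day 5), 1575 (RXRi day 1), 1061 (RXRi day 3), 2095 (RXRi day 4), 2699 (RXRi day 5), 169 (the atRA mean), 1598 (the RXRi mean) and 1892 (atRA against RXRi). Without the shallow library counts were 6830 (DMSO day 3 to 4), 428 (DMSO day 4 to 5), 431 (atRA day 1), 1080 (atRA day 3), 1361 (atRA day 4), 626 (atRA day 5), 5458 (RXRi day 3), 7340 (RXRi day 4), 7942 (RXRi day 5), 2854 (the atRA mean), 143 (the atRA change with time) and 5144 (the RXRi change with time). With scaling as well they were 6621 (DMSO day 3 to 4), 419 (DMSO day 4 to 5), 418 (atRA day 1), 1019 (atRA day 3), 1031 (atRA day 4), 657 (atRA day 5), 5421 (RXRi day 3), 7352 (RXRi day 4), 8131 (RXRi day 5), 2551 (the atRA mean), 146 (the atRA change with time) and 5422 (the RXRi change with time), and limma-voom on recovered reads gave 6990 (DMSO day 3 to 4), 362 (DMSO day 4 to 5), 319 (atRA day 1), 1143 (atRA day 3), 1564 (atRA day 4), 601 (atRA day 5), 5770 (RXRi day 3), 7616 (RXRi day 4), 7883 (RXRi day 5), 2837 (the atRA mean) and 77 (the atRA change with time).

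Median-of-ratios scaling and the culture as a block moved no count of genes by over 1.5 times. Under the block 111 genes changed between days 4 and 5 and 164 with atRA on day 5, 66 of 66 list results and 250 of 251 gene results kept their direction and side of the threshold. With only the groups compared, 192 of 251 gene results did, 57 lost their call, and 64 of 66 list results did. With an estimated correlation 56 list tests passed, against 293 with the preset one. Among the lists described, 39 of 66 results lost their call. With each culture or library left out in turn, a lone culture being assumed to vary like the other groups, counts ranged over 124 to 8729 (DMSO day 1 to 3), 1597 to 3213 (DMSO day 3 to 4), 38 to 112 (DMSO day 4 to 5), 517 to 7707 (the atRA mean), 14 to 8156 (the atRA change with time), 1919 to 8955 (the RXRi change with time), 24 to 8911 (atRA day 1), 604 to 9033 (RXRi day 1), 162 to 402 (atRA day 3), 1345 to 2429 (RXRi day 3), 82 to 271 (atRA day 4) and 71 to 254 (atRA day 5). For DMSO day 1 to 3, both drugs on day 1, the atRA mean and both changes with time, the highest count came from leaving out culture 2 of day 1 DMSO, which leaves the culture with the shallow library alone. Over the same alternatives the mean of the cholesterol list from day 1 to 3 ranged over 0.48 to 0.60, with its test turning to lower, and that of the enterocyte list with atRA on day 5 over -0.33 to 0.43. The correlation of atRA and RXRi effects on day 1 turned from 0.654 to -0.039 and -0.117 with the DMSO cultures divided between the drugs, and to -0.11 without the shallow library. Divided, it was -0.302 and -0.326 on day 3, -0.453 and -0.301 on day 4, and -0.312 and 0 on day 5, where the relation thus rests on the division. Depth is a limit in the day 1 DMSO group, in which 1 of 4 libraries cannot show genes of low level. What its reads are is a limit too, as a mixture of profiles gave 73.6% of them to days other than day 1. With and without it, the day 1 DMSO mean was, for example, 56.5 and 0.518 RPKM for Isx and 171 and 4.14 RPKM for Tff1.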

Other observations

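Genes of lists that the results have not described changed with RXRi too, not always in a common direction. Some tests in this part were chosen only after the results were seen. These were counts of draws that keep the real division of a day, splits that keep duplicates together and calls without a single library. On day 5, 7 of 17 measured interferon response genes rose (7 adjusted over the list alone), with Rsad2 (2.58 ± 0.26), Isg15 (2.09 ± 0.28) and Oas1a (1.22 ± 0.25), and 14 of 20 measured p53 targets rose and 2 fell (14 and 2 adjusted over the list alone), with Phlda3 (1.90 ± 0.20) and Plk2 (2.77 ± 0.33) higher and Sesn1 (-2.25 ± 0.27) lower. Of the M cell genes 6 of 7 measured genes rose and 1 fell (6 and 1 adjusted over the list alone), with Tnfaip2 (1.69 ± 0.36) and Ccl20 (1.84 ± 0.42) higher and Ccl9 (-2.48 ± 0.31) lower. Over the 4 days 12 of 13 measured replication-dependent histone genes rose (12 adjusted over the list alone), such as H1f2 (2.41 ± 0.20) and H2bc4 (1.96 ± 0.17); such transcripts mostly lack the poly(A) tail on which the library kit selects. In the tuft cell list Avil (3.32 ± 0.10) and Ptgs1 (1.44 ± 0.06) rose and Il17rb (-0.67 ± 0.08) fell, and 3 of 8 measured genes rose and 3 fell (3 and 3 adjusted over the list alone), with a mean of 0.54 and a median of -0.16. The list test gave adjusted p = 0.01 (adjusted p = 0.46 with an estimated correlation) for interferon, adjusted p = 1.4e-04 (adjusted p = 0.108 with an estimated correlation) for p53, adjusted p = 0.044 (adjusted p = 0.108 with an estimated correlation) for M cell (the call was lost, at adjusted p = 0.053, without duplicate 2 of DMSO culture 1) and adjusted p = 2.5e-04 (adjusted p = 0.171 with an estimated correlation) for histone genes.

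Vitamin D, fibroblast, immune, endothelial and mitochondrially encoded genes had too few measured members for a list test. S100g, a vitamin D target, reached 554 RPKM in an atRA day 5 library, with a median of 72.7 over the libraries other than the shallow one, and Cyp24a1 stayed at or below 0.027 RPKM. The fibroblast genes Col1a1 and Pdgfra and the leukocyte gene Ptprc stayed at or below 0.069, 0.053 and 0.014 RPKM in each of these libraries. Vim reached 23.9 RPKM in a day 0 library, and of the immune list Lyz2, Cd68 and Itgam reached 49.4, 7.63 and 3.61 RPKM (medians 16.3, 3.16 and 2.3). Across genes, the day 5 RXRi mean correlated with the DMSO means at r = 0.749 on day 0, 0.841 on day 1, 0.857 on day 3, 0.845 on day 4 and 0.806 on day 5, and the day 3 atRA mean at 0.956 on day 1, 0.981 on day 3 and 0.959 on day 4. Genes are not independent replicates.

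Other splits of the libraries were fitted with limma on the libraries of the groups compared, with duplicates as separate libraries. For 10 of the 12 comparisons of a pair of groups, 1 of 35 splits, the real one, gave as many genes, so chance could be excluded among splits that treat duplicates as independent. Of these splits 3 keep the duplicates of each culture together, too few for a share under 0.05, so between cultures the splits do not exclude chance. On culture means of the compared groups alone, limma called 0 genes for atRA on day 1, 3 for DMSO day 1 to 3 and 2 for RXRi on day 1. In this fit 255 genes had an unadjusted p under 0.05 for atRA on day 1, fewer than chance alone gives. The real and the highest other counts were 1917 and 0 for DMSO day 0 to 1, 80 and 0 for day 1 to 3, 7990 and 5 for day 3 to 4, 31 and 1, 3303 and 195, and 3930 and 952 for atRA on days 1, 3 and 4. For RXRi on days 1, 3, 4 and 5 they were 243 and 0, 8158 and 1, 8609 and 0, and 8415 and 0. For DMSO day 4 to 5 (657 genes) and atRA on day 5 (390), 2 of 35 splits gave as many and chance could not be excluded. The split by culture called 2800 and 1717 genes, so the cultures differed in these groups. Each culture comes from 1 animal, so the animal and the handling of its culture cannot be told apart. With the culture as a block in the fit of all groups, these comparisons called 111 and 164 genes. Over several days, 1 of 100 draws within days gave as many genes for atRA (1589, highest other 64), RXRi (6642 and 1), atRA against RXRi (10366 and 7968) and, narrowly, the atRA change with time (27 and 25). Among draws that divided no day as in reality the highest were 8, 0, 1 and 25. For the RXRi change with time 5 of 100 did (2104 and 3298), but the other 4 all kept the real division of a whole day and so carry that day's effect, and the draws do not decide whether chance gave this result. The 90 draws that divided no day as in reality gave at most 1.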
